A study of Mus musculus with 10 samples.

How the data were processed

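Small RNA sequencing was performed on RNA of small extracellular vesicles (sEVs, membrane particles that cells release) prepared from heart tissue of male C57BL/6J mice. Per the labels, mice assigned to the model received a diet with 60% fat together with L-NAME, an inhibitor of nitric oxide synthase, at 0.5 g/L in the drinking water. They were 8 weeks old at the start and stayed on the regimen for 12 weeks, a 2-hit model of heart failure with preserved ejection fraction (HFpEF). Control mice received chow. Vesicles were collected, per the labels, by collagenase digestion of minced heart, filtration and ultracentrifugation, and libraries were made with an adaptor-ligation kit for small RNA (MGIEasy). The preparation holds vesicles from any cell of the digested heart, not from cardiomyocytes alone.

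The deposited table gave a raw read count for 733 mature miRNAs in each of 10 libraries, of which 603 carried mouse miRNA names and 130 were predicted miRNAs without a registered name. The authors also deposited a second value for each count, whose header names no unit. It was assumed to be RPM, a count scaled by the authors to read depth, because the ratio of count to value was 1 constant per library, from which a library total was recovered. Which reads these totals cover is not stated in the sources used here, so shares of them and the alternative with read totals rest on that assumption. The deposited table also held group averages of both, which were not used here. The genome build was GRCm38.p6 per the submitters' processing notes, and the aligner, counting tool, annotation release and treatment of reads that match several miRNAs are not given in the sources used here. Miscounting of reads shared by miRNAs with identical sequence therefore could not be excluded from the descriptions.

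Libraries were grouped by the treatment label as control or HFD plus L-NAME, with 5 libraries each, and replicate numbers were given in accession order and pair nothing. The labels name no batch. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these libraries. Chi-square statistics per degree of freedom lay between 24.9 and 169 over the 20 pairs of libraries within a group and between 35.3 and 279 over the 25 pairs across groups, so no library was a copy of another.

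Counts were tested with edgeR 4.0.16 (TMM normalization, the default expression filter, robust quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 177 miRNAs, including 17 predicted ones, which held 99.7% of all counts. Standard errors were the log2 fold change divided by the square root of F. Levels are TMM-normalized CPM over miRNA counts, and log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 were run as alternatives. Lists of miRNAs were tested with limma's camera (preset correlation 0.01), camera with an estimated correlation and fry, for lists with at least 3 tested members. Values of single measures were compared by exact two-sided permutation tests over 252 arrangements (SciPy 1.17.1), whose smallest possible p is 0.00794. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used for the rest.

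The design, the 20 lists (192 entries, 15 of which had no row in the table), the alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule named the 10 most abundant miRNAs, up to 12 highest and 12 lowest among those past the threshold, the 10 smallest p where fewer than 10 passed, and the most abundant tested members of each list, for which it allowed 2 to 4. Up to 4 were taken from every list, which gave 63 named miRNAs. Smaller sets, with 2 members from some lists and none from others, were tried after values had been seen and were set aside because that choice left out values near 0 that change direction. Names outside the rule are marked where their results are given.

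Simulated counts were drawn from the means, library sizes and per-miRNA dispersions (spread between libraries) of the deposited counts, each miRNA independently. The test was checked on 10 simulations of the comparison of HFD plus L-NAME with control, with a median of 181 miRNAs tested. Among miRNAs that were simulated as changed and passed the filter, it called 11.7% at 1.5-fold, 34.2% at 2-fold and 92.5% at 4-fold. Changed miRNAs that the filter removed are not counted in these percentages. Of its calls, 3.92% were unchanged miRNAs. Without simulated change it called 0.2 miRNAs on average. Changes of 2-fold or less would thus often be missed with 5 libraries per group. The dispersions include those of miRNAs whose counts alternate between libraries, so these values hold for the simulated setting only.

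Precursor positions and host genes came from the GENCODE M21 annotation of GRCm38, in which 588 of the 603 named miRNAs (97.5%) had a precursor. Precursors were also compared for shared sequence. Pairs of mature miRNAs from precursors that share at least 22 bases in the same arm and hold at least 100 counts together were summed in an added alternative. That minimum of 22 bases and of 100 counts was set after shorter matches had been seen. The shared bases lie in the precursor arm, so the mature miRNAs of a summed pair need not be identical. Examples are miR-103-3p with miR-107-3p and miR-29b-3p with miR-29c-3p. All summed pairs are called copies below. The recovered library totals as library size, these sums, and both together were alternatives chosen after seeing the data. Intervals are exact Clopper-Pearson 95% intervals and limits for a count of 0 use 3 counts. Reads carried no molecular identifiers that the sources name, so both cover counting error only.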

Results

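The miRNA content of small extracellular vesicles from heart tissue was measured in 5 libraries of control mice and 5 libraries of mice on the high-fat diet with L-NAME (HFD plus L-NAME). The question, per the title of the series, concerns vesicles released in the heart in HFpEF. Between 238434 and 420828 miRNA counts were recorded per library, which was 0.980% to 1.85% of the 21563706 to 27493797 reads that a second deposited value implies if it is RPM. A count of 0 allowed a level of up to 7.13 to 12.6 CPM, depending on the library. The mean was 343348 ± 73358 counts (SD, n = 5) in control and 285424 ± 32816 in HFD plus L-NAME (exact permutation p = 0.143, adjusted over 8 library measures 0.229). On that assumption the miRNA share of these reads was 1.52% ± 0.350 in control and 1.20% ± 0.216 in HFD plus L-NAME (n = 5 each, exact permutation p = 0.119, adjusted 0.229). Without control 5 alone, that p was 0.0317 by the exact test. At least 1 count was found for 415.8 ± 15.4 miRNAs per control library and 400.2 ± 21.7 per HFD plus L-NAME library (exact permutation p = 0.246, n = 5). With a library left out, this difference ranged from -22.55 to -7.55 miRNAs. Predicted miRNAs took 0.390% ± 0.0371 of counts in control and 0.443% ± 0.148 in HFD plus L-NAME.

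The vesicles of both groups were dominated by miR-1a-3p, the muscle miRNA encoded by Mir1a-1 (chromosome 2, 180389048 to 180389124) and Mir1a-2 (chromosome 18, 10785481 to 10785552, in an intron of Mir133a-1hg; GRCm38 throughout). It took 24.6% ± 4.10 of miRNA counts in control and 33.9% ± 6.17 in HFD plus L-NAME (n = 5 each), with an exact permutation p of 0.0317 that became 0.229 after adjustment over the 8 library measures. For single libraries the exact 95% interval was narrow, for example 43.5% to 43.9% around 43.7% in HFD plus L-NAME 5. Leaving out control 1, control 4, control 5, HFD plus L-NAME 2, HFD plus L-NAME 4 or HFD plus L-NAME 5 each gave an exact p of 0.0635. The next most abundant were miR-126a-3p of endothelial cells, whose precursor lies within the gene Egfl7, and miR-378a-3p, in an intron of Ppargc1b. They were followed by let-7f-5p, miR-26a-5p, miR-143-3p, miR-99a-5p, miR-22-3p, miR-1b-5p and miR-27b-3p. On the log2 scale, miR-26a-5p differed by -0.49 ± 0.17 between HFD plus L-NAME and control, miR-99a-5p by -0.38 ± 0.16, miR-22-3p by -0.23 ± 0.18 and miR-1b-5p by 0.10 ± 0.19 (SE, edgeR), and none of these passed the adjusted threshold. The counts of miR-1b-5p are uncertain, since its precursor lies antisense to Mir1a-2.

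By edgeR 0 miRNAs passed the adjusted threshold between HFD plus L-NAME and control (28 at an unadjusted p under 0.05), by limma 0 and by DESeq2's Wald test 3 (miR-499-5p, miR-125b-5p and miR-23a-3p). The lowest edgeR p belonged to miR-499-5p, a cardiac miRNA from an intron of the myosin gene Myh7b (chromosome 2, 155622880 to 155622958), at 34744 ± 3709 CPM in control and 22924 ± 2527 CPM in HFD plus L-NAME (SD, n = 5 each). Lower values were also recorded for miR-125b-5p (1650 ± 385 against 962 ± 211 CPM), miR-143-3p of smooth muscle (48127 ± 9444 against 33098 ± 4518 CPM) and miR-23a-3p (16047 ± 1319 against 11864 ± 933 CPM). Higher values were recorded for miR-214-3p, from an exon of Dnm3os (chromosome 1, 162223368 to 162223477), at 43.9 ± 8.12 CPM in control and 94.6 ± 38.3 CPM in HFD plus L-NAME.

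Of 177 miRNAs tested, edgeR's quasi-likelihood test called 0 at an adjusted p of 0.05, while 28 had an unadjusted p under 0.05, 13 higher and 15 lower in HFD plus L-NAME. The latter count was 18 without control 5 and 17 without HFD plus L-NAME 5. The smallest adjusted p was 0.172. DESeq2's Wald test called 3 miRNAs, all lower (miR-499-5p, miR-125b-5p and miR-23a-3p, with adjusted p of 0.00492, 0.0362 and 0.0466), and limma with trend called 0, with 29 and 26 at an unadjusted p under 0.05. With the recovered read totals as library size, chosen after seeing the data, edgeR also called 0, and the 38 miRNAs at an unadjusted p under 0.05 were 1 higher and 37 lower. They were 18 higher and 9 lower with the most abundant miRNA removed, 16 and 5 without control 4, and 4 and 13 without HFD plus L-NAME 5, so this balance depends on the setting.

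By edgeR, miR-499-5p differed by -0.60 ± 0.15 on the log2 scale (SE, adjusted p = 0.172). The other miRNAs with the 10 smallest p were miR-125b-5p (-0.78 ± 0.22), miR-214-3p (1.09 ± 0.33), miR-150-5p of lymphocytes (-1.01 ± 0.31) and miR-148a-3p (0.78 ± 0.24). They also included miR-143-3p (-0.54 ± 0.17), miR-23a-3p (-0.44 ± 0.14), miR-92a-3p (-0.96 ± 0.31), miR-335-5p from an intron of Mest (1.28 ± 0.42) and miR-199b-5p (0.85 ± 0.29). Their adjusted p by edgeR lay between 0.172 and 0.200. By TMM-normalized CPM, in 7 miRNAs the 5 libraries of one group all lay above those of the other, 3.95% of those tested, where chance gives 0.794%. These were miR-499-5p, miR-125b-5p, miR-143-3p and miR-23a-3p, lower in HFD plus L-NAME, and miR-214-3p, miR-29a-3p and miR-103-3p, higher. Of the higher ones, miR-103-3p was named after its values were seen and had 55.0 ± 17.9 CPM in control and 96.7 ± 24.2 CPM in HFD plus L-NAME. Its separate count is uncertain, since miR-107-3p is a near-identical copy. As a sum of both, in CPM without TMM, the groups overlapped, with 76.0 in control 2 and 66.8 in HFD plus L-NAME 2. Scaled to read totals, miR-103-3p by itself overlapped too. Control 2 held 28 counts in 23494410 reads, and HFD plus L-NAME 2 held 18 in 23608240. In assumed RPM, miR-29a-3p had 5.83 ± 1.26 in control and 6.68 ± 1.70 in HFD plus L-NAME, and miR-214-3p 0.691 ± 0.272 and 1.09 ± 0.378. The 4 lower ones kept lower means there, for example 750 ± 307 against 396 ± 93.7 for miR-143-3p. The groups of miR-499-5p, miR-143-3p and miR-23a-3p nevertheless overlapped on that scale, and those of miR-125b-5p stayed apart narrowly. The separation of the higher ones and of most lower ones thus depends on the scaling.

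**Figure D1:**
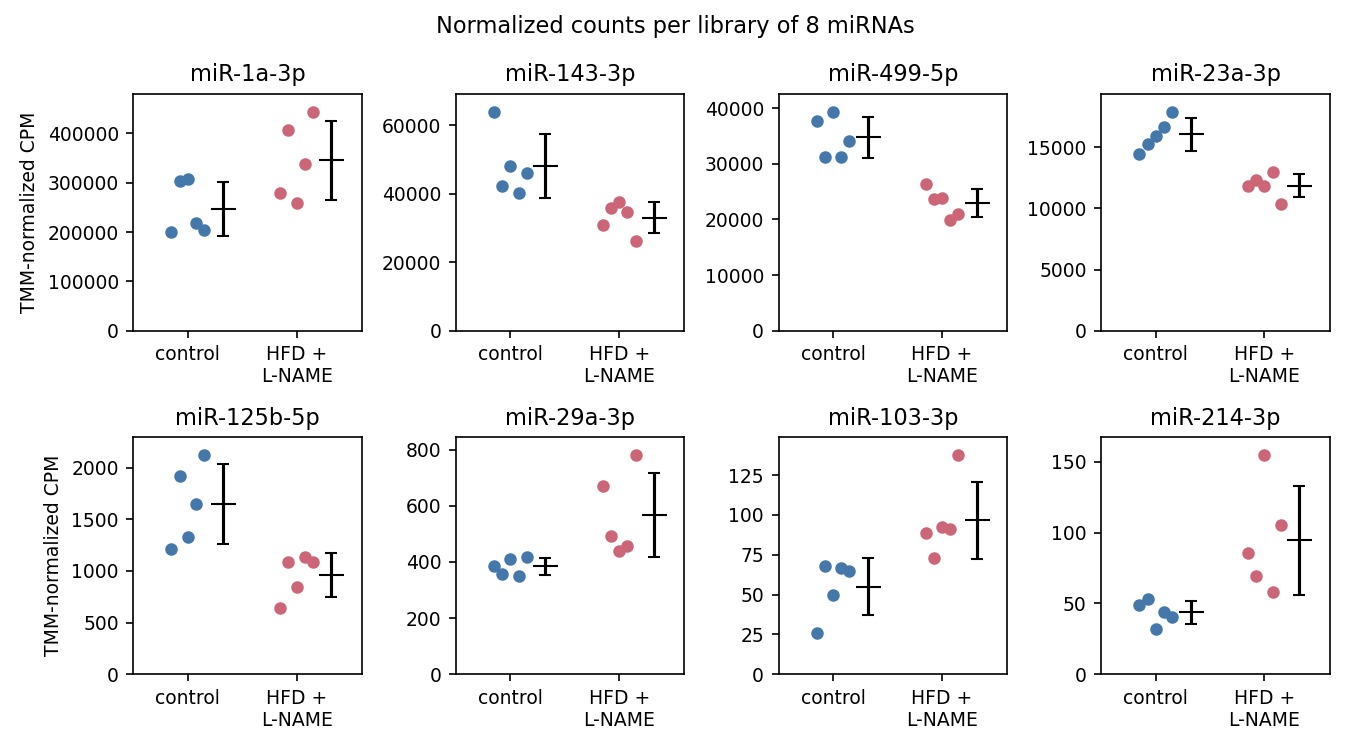
Each panel shows 1 miRNA, with TMM-normalized CPM on the vertical axis from 0, 1 point per library (5 control, 5 HFD plus L-NAME) and the mean with its SD as a bar beside the points. The groups of miR-143-3p, miR-499-5p, miR-23a-3p, miR-125b-5p, miR-29a-3p, miR-103-3p and miR-214-3p do not overlap, and those of miR-1a-3p do.

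The muscle miRNAs did not move together. Of 7 tested, 4 had higher and 3 lower values in HFD plus L-NAME. In log2 units, miR-1a-3p differed by 0.48 ± 0.20, miR-208a-3p, from an intron of the myosin gene Myh6, by 0.63 ± 0.24, miR-499-5p by -0.60 ± 0.15 and miR-133a-3p by -0.19 ± 0.23. Over all miRNAs 0 of the 7 passed by edgeR and miR-499-5p did by DESeq2's Wald test (adjusted p = 0.00492), and 4 passed by edgeR when adjusted over the list alone (miR-1a-3p, miR-208a-3p, miR-499-5p and miR-1a-1-5p, the last named after its values were seen). Camera gave the list an adjusted p of 0.645. The list took 29.2% ± 3.84 of counts in control and 37.3% ± 5.80 in HFD plus L-NAME (n = 5, exact permutation p = 0.0317, adjusted 0.212). Without miR-1a-3p in the total, that difference was -1.04 percentage points.

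The fibroblast and fibrosis miRNAs had higher values in 8 of 9 tested. They included miR-21a-5p (0.27 ± 0.20), miR-29a-3p (0.56 ± 0.21), miR-145a-5p (0.18 ± 0.23) and miR-199a-3p (1.01 ± 1.39). Both miR-214-3p and miR-199b-5p, from genes active in mesenchymal cells, are members, whereas the miR-29 family is known to repress collagen genes. The 1 lower member was miR-199a-5p (-0.13 ± 0.41), named after its values were seen. Camera with its preset correlation called the list, higher in HFD plus L-NAME, at an adjusted p of 0.0273. The adjusted p was 0.696 with an estimated correlation and 0.294 with fry. Of the members 0 passed by edgeR over all miRNAs and 1, miR-214-3p, when adjusted over the list alone. The camera call was lost without control 1 (adjusted p = 0.121), control 2 (0.0780), HFD plus L-NAME 1 (0.116), HFD plus L-NAME 3 (0.0599) or HFD plus L-NAME 5 (0.102), and with read totals as library size (0.0573), where the median of the list was -0.13. The list took 0.749% ± 0.260 of counts in control and 1.11% ± 0.428 in HFD plus L-NAME (n = 5, exact permutation p = 0.151). In control 1, control 4 and HFD plus L-NAME 5 this share leaves out counts named miR-199b-3p, which is not on the list and whose reads may belong to miR-199a-3p. The difference of 0.360 percentage points was 0.196 without HFD plus L-NAME 3.

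The miRNAs reported as selectively sorted into vesicles had lower values in 6 of 7 tested, among them miR-451a, miR-143-3p, miR-150-5p and miR-223-3p. Of its members miR-451a and miR-486a-5p are also on the red blood cell list, miR-143-3p, the most abundant, on the smooth muscle list, and miR-150-5p and miR-223-3p on the leukocyte list, so its values are not independent of those lists, of which the first 2 also had lower shares. Camera gave an unadjusted p of 0.0164 and an adjusted p of 0.139, and the adjusted p was 0.696 with an estimated correlation. With copies summed, an alternative chosen after seeing the data, the list was called lower by camera (adjusted p = 0.00933) and by fry (0.0357) but not with an estimated correlation (0.262). Its 1 higher member, miR-486a-5p, has an uncertain count and was lower as a sum with miR-486b-5p (-0.73). Camera also called the list without control 3 (0.0382). Over all miRNAs 0 members passed by edgeR, and 3 passed when adjusted over the list alone (miR-451a, miR-150-5p and miR-143-3p). The list took 8.38% ± 1.77 of counts in control and 5.11% ± 1.09 in HFD plus L-NAME (n = 5, exact permutation p = 0.0159, adjusted 0.159).

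Of the red blood cell, smooth muscle, endothelial and leukocyte lists, 0 passed limma's camera or fry or the exact test of shares after adjustment, while for single miRNAs miR-143-3p and miR-150-5p passed by edgeR when adjusted over their list alone. Shares are parts of 1 total, in which miR-1a-3p took 24.6% in control and 33.9% in HFD plus L-NAME. Part of a lower share of these lists, and of the vesicle-sorted list, can follow from that alone. The red blood cell list took 3.45% ± 1.82 of counts in control and 1.78% ± 0.706 in HFD plus L-NAME (n = 5, exact permutation p = 0.0952, adjusted 0.282). Its main member miR-451a stood at 33478 ± 17936 CPM in control and 17142 ± 5866 CPM in HFD plus L-NAME, a log2 difference of -0.97 ± 0.35. Control 2 and control 4 held 52138 and 53459 CPM. The other control libraries held 17267 to 25803 CPM, against 8886 to 25469 CPM in HFD plus L-NAME. Further log2 differences were -1.30 ± 0.49 for miR-486b-5p, 0.51 ± 0.94 for miR-486a-5p and -0.14 ± 0.39 for miR-144-3p. The precursors of both miR-486 forms share 22 bases in that arm, so their separate counts are uncertain, and their sum differed by -0.73. Of its 6 tested members 0 passed by edgeR over all miRNAs or when adjusted over the list alone, and camera gave an adjusted p of 0.742.

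Smooth muscle and pericyte miRNAs took 5.10% ± 1.12 of counts in control and 3.56% ± 0.534 in HFD plus L-NAME, with an exact permutation p of 0.00794, the smallest that 5 against 5 allows, and 0.159 after adjustment over the 20 lists. In that list miR-143-3p differed by -0.54 ± 0.17, miR-145a-5p by 0.18 ± 0.23 and miR-145a-3p by -0.23 ± 0.26. Over all miRNAs 0 of 3 passed by edgeR and 1, miR-143-3p, when adjusted over the list alone. Endothelial miRNAs took 7.17% ± 0.657 and 5.75% ± 1.19 (exact permutation p = 0.0556, adjusted 0.278, n = 5). The log2 differences were -0.32 ± 0.18 for miR-126a-3p and 0.40 ± 0.23 for miR-126a-5p, the 2 arms of one precursor, and miR-221-3p differed by -0.05 ± 0.27 and miR-222-3p by -0.69 ± 0.42. Leukocyte miRNAs took 0.479% ± 0.0328 and 0.471% ± 0.129 (exact permutation p = 0.897, n = 5) and had 3 higher and 2 lower values, with miR-146a-5p at 0.09 ± 0.24, miR-155-5p at 0.44 ± 0.27, miR-223-3p at -0.24 ± 0.32 and miR-150-5p at -1.01 ± 0.31. Over all miRNAs 0 of 5 passed by edgeR and 1, miR-150-5p, when adjusted over the list alone. Control 4 and control 5 held 888 and 829 CPM of miR-150-5p. The other control libraries held 370 to 393 CPM, against 211 to 429 CPM in HFD plus L-NAME. The leukocyte median was 0.09, its mean -0.08 and its camera direction lower. Camera gave adjusted p of 0.645 for smooth muscle, 0.742 for endothelial and 0.888 for leukocyte miRNAs.

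Markers of distant tissues were scarce. Liver miRNAs took 0.0633% ± 0.0163 and 0.0493% ± 0.00562 of counts in control and HFD plus L-NAME (exact permutation p = 0.0794, n = 5), with miR-192-5p at -0.12 ± 0.19 and miR-194-5p at -0.23 ± 0.32. Of the neuronal list miR-128-3p was tested, at -0.12 ± 0.28, and of the epithelial and endocrine list miR-429-3p, at 0.34 ± 0.47. These 3 lists had too few tested members for camera, and 0 of their members passed by edgeR when adjusted over the list alone or over all miRNAs.

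Heart failure and hypertrophy miRNAs had 5 higher and 4 lower values, with miR-34a-5p at -0.32 ± 0.20, miR-23a-3p at -0.44 ± 0.14, miR-24-3p at 0.36 ± 0.19 and miR-21a-5p at 0.27 ± 0.20. Over all miRNAs 0 passed by edgeR and miR-23a-3p did by DESeq2's Wald test (adjusted p = 0.0466), 3 passed by edgeR when adjusted over the list alone (miR-23a-3p, miR-199b-5p and miR-214-3p), and camera gave an adjusted p of 0.430. Nitric oxide and vascular tone miRNAs had 4 higher and 5 lower values, with miR-126a-3p and miR-24-3p the most abundant. Of these 0 passed by edgeR over all miRNAs and 2, miR-92a-3p and miR-125b-5p, when adjusted over the list alone (limma camera adjusted p = 0.822), and miR-125b-5p passed over all miRNAs by DESeq2's Wald test (adjusted p = 0.0362). Inflammation-responsive miRNAs had 3 higher and 3 lower values, with miR-181a-5p at -0.59 ± 0.22, and 0 passed by edgeR over all and 1, the same miR-125b-5p, when adjusted over the list alone (limma camera adjusted p = 0.731). Lipid and glucose metabolism miRNAs had 5 higher and 3 lower values, with miR-378a-3p at 0.06 ± 0.16, miR-27b-3p at 0.06 ± 0.20 and miR-27a-3p at -0.08 ± 0.19. Of these 0 passed by edgeR over all miRNAs or when adjusted over the list alone (limma camera adjusted p = 0.749).

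In the sequence families and clusters 0 members passed over all miRNAs by edgeR, while by DESeq2's Wald test miR-23a-3p did (adjusted p = 0.0466). In the let-7 and miR-98 family 4 of 9 values were higher, with let-7f-5p at 0.32 ± 0.26, let-7g-5p at 0.04 ± 0.26, let-7c-5p at -0.26 ± 0.27 and let-7i-5p at 0.08 ± 0.26, and camera gave an adjusted p of 0.822. In the miR-30 family 4 of 5 were higher (limma camera adjusted p = 0.645), with miR-30d-5p at -0.19 ± 0.20, miR-30b-5p at 0.09 ± 0.16, miR-30c-5p at 0.07 ± 0.15 and miR-30a-5p at 0.11 ± 0.19. The miR-15 and miR-16 family had 4 of 6 higher (limma camera adjusted p = 0.645), with miR-16-5p at 0.43 ± 0.18, miR-195a-5p at 0.89 ± 0.35, miR-322-5p at -0.27 ± 0.29 and miR-497a-5p at 0.03 ± 0.24. When adjusted over the list alone 0 members passed by edgeR in these 3 families. Of the miR-17 cluster and its paralogues 1 of 4 was higher (limma camera adjusted p = 0.645), with miR-25-3p at -0.16 ± 0.24, miR-93-5p at -0.16 ± 0.20 and miR-19b-3p at 0.05 ± 0.39, and miR-92a-3p passed when adjusted over the list alone. Of the miR-23, miR-27 and miR-24 clusters 3 of 6 were higher, with miR-23b-3p at -0.09 ± 0.17, a camera direction of higher against a median of -0.01 (limma camera adjusted p = 0.949), and miR-23a-3p passed when adjusted over the list alone. Of the Dlk1-Dio3 imprinted cluster 1 of 5 was higher, with miR-411-5p at -0.12 ± 0.19, miR-127-3p at -0.11 ± 0.27, miR-379-5p at 0.08 ± 0.21 and miR-154-5p at -0.23 ± 0.26, and 0 passed when adjusted over the list alone (limma camera adjusted p = 0.742).

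Of the 17 lists tested, camera with the preset correlation called 1, and camera with an estimated correlation and fry called 0 each. The mixed form of fry asks whether members change in either direction, without comparing them with the other miRNAs. It called 5: muscle, heart failure and hypertrophy, nitric oxide and vascular tone, inflammation-responsive, and vesicle-sorted miRNAs, at adjusted p of 0.0111 to 0.0288. Some of these lists share members, such as miR-125b-5p, and the calls were not checked on regrouped libraries. Exact tests of list shares called 0 of 20 after adjustment.

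**Figure D2:**
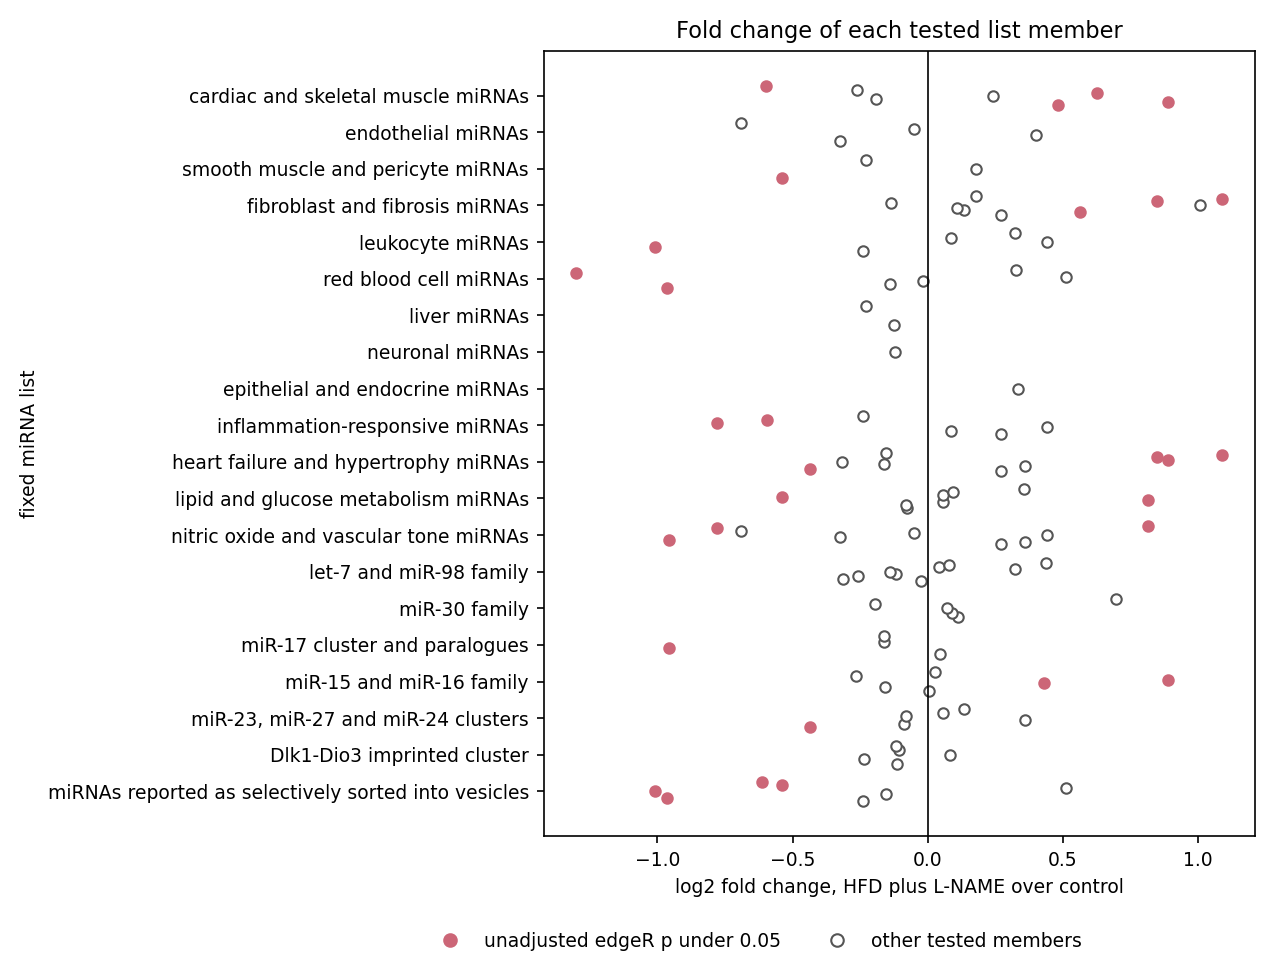
Each row is a fixed miRNA list and each point a tested member, placed by its log2 fold change of HFD plus L-NAME over control on the horizontal axis, with filled points for an unadjusted edgeR p under 0.05. Members of the muscle list lie on both sides of 0, and 8 of the 9 fibroblast and fibrosis members lie above it.

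Counts of miR-199a-3p and miR-199b-3p, whose precursors share 28 bases in that arm, alternated between libraries. In control 1, control 4 and HFD plus L-NAME 5, miR-199b-3p held 98.75%, 98.97% and 98.90% of their joint counts, and in the other 7 libraries it held at most 1.14%. Their separate values are therefore uncertain, and miR-199b-3p was named after its values were seen. The sum differed by 0.53 ± 0.24 between HFD plus L-NAME and control (edgeR adjusted p = 0.2505).

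**Figure D3:**
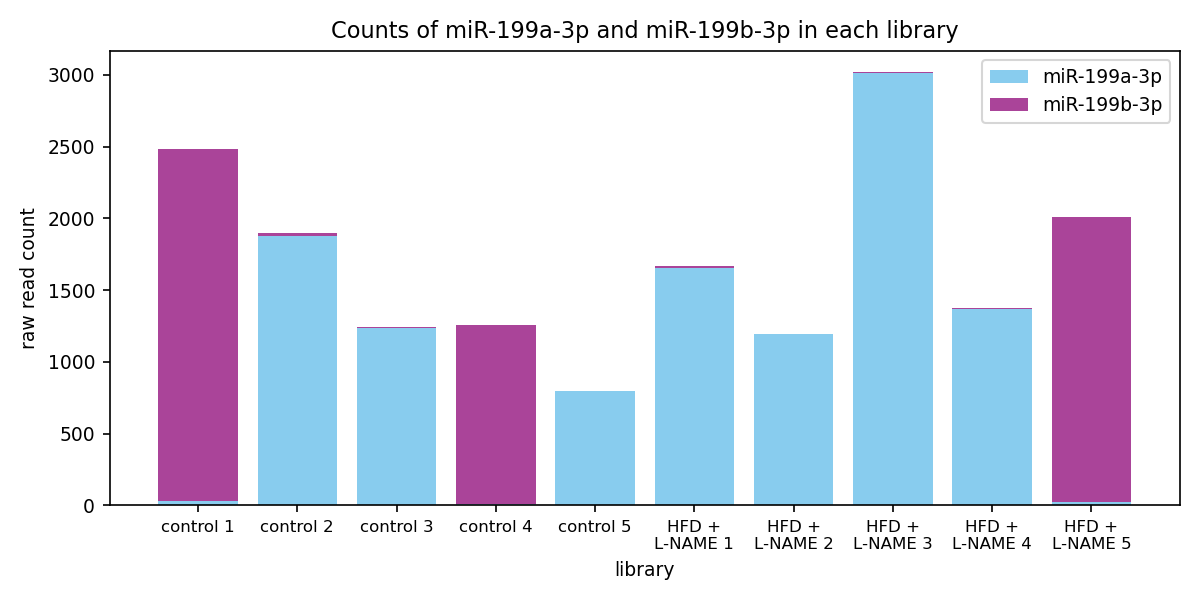
Stacked bars give the raw read counts of miR-199a-3p and miR-199b-3p on the vertical axis in each of the 10 libraries. In control 1, control 4 and HFD plus L-NAME 5 nearly all counts carry the name miR-199b-3p, and in the other 7 libraries miR-199a-3p.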

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

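The tests of the miR-199 counts were chosen after the result was seen.

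In 8 of 178 groups of 5 libraries examined, 1 library lay far from the other 4, where chance gives about 8.9. Control 1 held 45517 CPM of miR-27b-3p, against 26190 in the nearest control library. The same library held 13700 CPM of miR-24-3p (nearest 9118) and 634 CPM of miR-195a-5p (nearest 276). Its share of smooth muscle and pericyte miRNAs was 7.03% (nearest 5.11%) and that of lipid and glucose metabolism miRNAs 20.6% (nearest 14.0%). HFD plus L-NAME 4 held 2943 CPM of miR-126a-5p (nearest 2095), and control 5 held 114 CPM of miR-145a-3p (nearest 79.9). Control 2 had a share of nitric oxide and vascular tone miRNAs of 7.11% (nearest 8.43%).

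The alternation of miR-199a-3p and miR-199b-3p between libraries may reflect reads of identical copies that were given to 1 name per library. The SD of their summed log2 CPM, 0.482, lay at percentile 85.1 among 47 other miRNAs above 1000 CPM, not far under the 90th that was set as the bound, against SDs of 3.03 and 3.97 for each alone. A switch of the transcribed gene is argued against by the 5p arms, in which the miR-199b-5p percentage spanned 31.8 points, from 38.3% to 70.1%. The regimen is argued against because the miR-199b-3p percentage spanned at least 98.8 points within each group (exact permutation p = 0.405 between groups). How the counts were assigned stays open, and let-7a-1-3p and let-7c-2-3p, named after their values were seen, alternated too, with let-7c-2-3p at 97.4% to 100% of 18 to 38 joint counts in 5 libraries and at 0% to 8.70% of 18 to 39 in the other 5.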

How the results depend on the processing

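The alternatives that use read totals, sums of copies, or both were chosen after seeing the data. The others were set before. Of 1306 values of the 63 named miRNAs under an alternative, 1200 kept their direction and their side of the threshold, 8 passed it and 98 changed direction, while 35 of the miRNAs never changed direction in these alternatives. The number of miRNAs called, 0 by edgeR, became 3 with DESeq2's Wald test, 5 with copies summed and read totals as library size (miR-150-5p, miR-149-5p, miR-92a-3p, miR-125b-5p and miR-499-5p, all lower) and 1 without the filter. That one, miR-200c-3p, had 0 to 3 counts in each control library and 2 to 10 in each HFD plus L-NAME library; it and miR-149-5p were named after their values were seen. The number remained 0 by edgeR with DESeq2 size factors, library size alone, the stricter filter, a threshold of 0.1, red blood cell miRNAs or the most abundant miRNA removed, copies summed or read totals, and by limma. Without control 1 edgeR called 1 (miR-148a-3p) and without control 2 it called 1 (a predicted miRNA); the range over left-out libraries was 0 to 1. The count at an unadjusted p under 0.05 was 68 without the filter, and 17 to 34 with a library left out, the lowest being 18 without control 5 and 17 without HFD plus L-NAME 5. The median log2 fold change of all tested miRNAs was -0.02, and moved to -0.38 with read totals, -0.39 with copies summed as well, 0.12 with the most abundant miRNA removed, 0.11 without the filter, 0.12 without control 3 and 0.11 without control 4, so directions under these are relative to such a shift. The number of lists called was 0 with an estimated correlation, 0 with fry, 0 with read totals, 2 with copies summed (fibroblast and fibrosis, and vesicle-sorted miRNAs) and 0 to 2 with a library left out (the same 2 without control 3). The adjusted p of the fibroblast and fibrosis list was 0.696 with an estimated correlation, 0.294 with fry, 0.0573 with read totals and 0.00168 to 0.121 with a library left out. The number of list shares past adjustment was 0 in each alternative run. The difference in miR-1a-3p share ranged from 6.88 to 10.9 percentage points with a library left out, that in miRNA counts from -84152 to -38554 and that in the miRNA share of reads from -0.457 to -0.239 percentage points; without control 5 the exact permutation p of the last 2 was 0.0317. The difference in muscle list share reversed to -1.04 percentage points without the most abundant miRNA. The cause of these changes was not tested.

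Log2 fold changes that changed direction mostly lay close to 0 or moved with the scale, except for miR-486a-5p, whose precursor shares sequence with that of miR-486b-5p. Without the filter the direction changed for miR-221-3p (0.0030), with the stricter filter for miR-221-3p (0.019), and with limma for let-7g-5p (-0.054), let-7i-5p (-0.018) and miR-19b-3p (-0.050). With red blood cell miRNAs removed it changed for miR-378a-3p (-0.00089), miR-27b-3p (-0.023), let-7g-5p (-0.030) and miR-497a-5p (-0.019). With the most abundant miRNA removed it changed for miR-221-3p (0.073), miR-144-3p (0.012), miR-192-5p (0.014), miR-128-3p (0.035), miR-27a-3p (0.036), miR-23b-3p (0.059), miR-411-5p (0.0030) and miR-127-3p (0.019). With read totals as library size it changed for miR-378a-3p (-0.32), miR-1b-5p (-0.27), miR-27b-3p (-0.36), miR-145a-5p (-0.14), miR-21a-5p (-0.13), miR-146a-5p (-0.33), miR-24-3p (-0.036), let-7g-5p (-0.26), let-7i-5p (-0.22), miR-30b-5p (-0.26), miR-30c-5p (-0.30), miR-30a-5p (-0.25), miR-19b-3p (-0.32), miR-497a-5p (-0.33) and miR-379-5p (-0.34). With copies summed it changed for miR-378a-3p (-0.0038), miR-27b-3p (-0.00068), miR-486a-5p (-0.73), let-7g-5p (-0.015), miR-19b-3p (-0.018) and miR-497a-5p (-0.030). With both it changed for the miRNAs named for read totals, at the same values to 2 decimals, and for miR-486a-5p (-1.04). With a library left out, the values of these miRNAs ranged over 0: miR-221-3p (-0.20 to 0.19), miR-27a-3p (-0.17 to 0.12), let-7g-5p (-0.13 to 0.21), miR-19b-3p (-0.12 to 0.34), miR-497a-5p (-0.13 to 0.28), miR-411-5p (-0.25 to 0.025) and miR-192-5p (-0.22 to 0.0035). The same held for miR-23b-3p (-0.17 to 0.026), miR-127-3p (-0.25 to 0.056), miR-223-3p (-0.39 to 0.026), miR-144-3p (-0.35 to 0.18), miR-128-3p (-0.33 to 0.066), miR-25-3p (-0.29 to 0.074) and miR-93-5p (-0.25 to 0.049). It also held for miR-322-5p (-0.36 to 0.0048), miR-378a-3p (-0.094 to 0.17), miR-27b-3p (-0.058 to 0.28), miR-486a-5p (-0.14 to 1.74), miR-30a-5p (-0.046 to 0.26), miR-146a-5p (-0.045 to 0.29), let-7i-5p (-0.055 to 0.27), miR-379-5p (-0.049 to 0.24) and miR-1b-5p (-0.079 to 0.30). The cause was not tested. Depth limits miRNAs under about 12.6 CPM, the level that a count of 0 allows in the shallowest library.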

Other observations

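The tests with summed copies and those of miR-1b-5p were chosen after the result was seen, and the estimated correlation, set beforehand, was taken as a test of the list call after its result was seen.

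The number of miRNAs called by edgeR was 0 in the real split, with up to 2 in another split; all of the 100 splits of the 10 libraries into 5 and 5 that were examined gave as many, as any split must where the real count is 0, so this says nothing about chance. At an unadjusted p under 0.05 the real split gave 28 miRNAs, and 2 of the 100 splits, the real one included, gave at least as many. That was under the 5% set beforehand and argues against chance for that count with all 10 libraries. It does not exclude chance, since 1 split of mixed libraries gave 29. Without control 5 the count was 18 and without HFD plus L-NAME 5 it was 17, for which no splits were run. Camera called 1 list in the real split, and 51 of 100 splits called as many, with up to 3 in another, so chance was not excluded for the list call.

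The call of the fibroblast and fibrosis list, with members such as miR-214-3p (1.09 ± 0.33) and miR-29a-3p (0.56 ± 0.21), may rest on correlation among its members. With the correlation estimated at 0.358 in place of 0.01 the adjusted camera p was 0.696, where each log2 difference stayed as it was and the spread allowed for the list grew, so this concerns the call and not the higher values. The part of reads shared between miR-199a-3p and miR-199b-3p in the call was not isolated. With all copies summed the adjusted camera p was 0.00933 (0.634 with an estimated correlation as well). Those sums also merged the members miR-29b-3p (0.13 ± 0.35) and miR-29c-3p (0.11 ± 0.25), which left 8 tested. The call thus remained with the sums, which cannot show what the miR-199 reads contribute. Whether dominance of miR-1a-3p in the counts bears on the higher values was not decided. Its removal moved each of the 176 miRNAs compared up, by 0.0697 to 0.190 in log2 units. Such a shift follows from its higher share in HFD plus L-NAME and is no separate test. The camera test cannot decide it either, since a shift nearly alike (median 0.141, SD 0.0161) hardly enters a comparison with the other miRNAs. The adjusted camera p with miR-1a-3p removed was 0.0244. With read totals as library size the median of the list was -0.13, so its higher values hold relative to the miRNA counts. A change in fibroblast vesicles under the regimen remains an untested hypothesis.

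The miRNA miR-1b-5p is annotated on a precursor (chromosome 18, 10785446 to 10785567, plus strand, in an intron of Mib1) that contains the reverse complement of the 72 bases of Mir1a-2. Its counts were 12.0% ± 0.644 of those of miR-1a-3p in control and 9.18% ± 0.822 in HFD plus L-NAME (SD, n = 5), 1 ratio chosen for this antisense position after the counts had been seen, with an exact permutation p of 0.00794, the smallest possible. One fixed share of miR-1a-3p reads under the name miR-1b-5p is argued against as the whole source, since the libraries held 11.2% to 12.7% in control and 8.11% to 10.1% in HFD plus L-NAME. Counting on either strand is argued against by 7 other antisense pairs with at least 1000 counts. Their less abundant partner held a median of 0.021% and at most 0.734%. This leaves out miR-486a and miR-486b, also an antisense pair, at 61.5%, where shared sequence and strand cannot be told apart. Where the miR-1b-5p reads come from was not resolved, and an effect of the regimen on the ratio stays a hypothesis.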
